A study of Homo sapiens with 12 samples.

How the data were processed

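RNA sequencing libraries of IMR-90 human fetal lung fibroblasts were made from total RNA with a TruSeq kit and sequenced on an Illumina GAIIx, per the labels' protocols. Lentiviral particles came from HEK-293T cells, a packaging line. One table holds 63129 gene entries for 12 libraries as FPKM, which the authors deposited, and 1 stray header line inside it was removed. TopHat2, HTSeq and Cuffdiff and the genome build hg19 are named in the submitters' processing notes. Their versions, the annotation release and which tool made the FPKM values are not given in the sources used here. FPKM divides by transcript length and by mapped fragments of the library, so values are relative to the rest of each library and are not counts, and no count model was used. Whether counting used strand is not given, so antisense partners are not told apart. Gene symbols are those of the table, and gene types and names came from GENCODE 29 by Ensembl identifier, for a newer assembly than hg19, so no coordinates are given. Of the identifiers 51653 matched, and 1205 of the tested genes had no gene type.

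Libraries were grouped by the treatment that each label names, into 4 groups of 3. No 2 libraries held identical values. The sum of FPKM was 721893 to 948334 per library. The 10 highest genes took 17.4 to 22.6% of it, except 37.4% in BRAF replicate 1. Absolute depth is unknown. The commonest ratio of low values to those of vector replicate 1 gave relative depths from 0.807 to 1.06, but that ratio held for only 4.60 to 9.09% of low-value genes, so it is a rough guide. Short RNA genes, 669 of the tested genes, have unstable FPKM. Some zeros may be failed estimates: 24 protein-coding genes were at 0 in some libraries of a group in which another library held 10 FPKM or more. Genes at 0 are therefore described as listed at 0.

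Values were analysed as log2(FPKM + 1) for the 17285 genes with a mean of at least 1 FPKM over the 12 libraries, 11713 of them protein-coding. All libraries entered 1 limma fit with eBayes and a mean-variance trend, which left 8 residual degrees of freedom. The 7 contrasts were BRAF, DNMT3B and DNMT3B+BRAF each against vector, DNMT3B+BRAF against BRAF and against DNMT3B, the interaction (the DNMT3B effect with BRAF minus that without), and the mean of those DNMT3B effects. Tests were two-sided with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A gene was called higher or lower at that threshold, whatever its fold.

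Named genes followed a fixed rule. DNMT3B and BRAF were always named. For each contrast the rule took the 10 highest and 10 lowest fold changes among genes past the threshold with no overlap between the libraries of both groups, with no overlap rule for the interaction and the averaged effect. For each list it took up to 4 members past the threshold with the largest changes, or the 2 highest members where none passed. Entries without a single gene symbol were counted and not named. From these genes the text names a part. Where the rule required them, passing the threshold and no overlap are no added support for the named genes.

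Gene lists, 21 in number and drawn from textbook knowledge, were cell cycle inhibitors, senescence secretory genes, DNA replication, mitosis, ERK pathway output, fibrillar matrix, contractile and TGF-beta response genes, DNA methylation machinery, CIMP markers (the CpG island methylator phenotype), germline genes, p53 targets, interferon response, lysosome and autophagy, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, ribosomal protein and housekeeping genes, and epithelial, endothelial and blood cell markers. The 20 lists with more than 1 tested member were tested with limma camera at a preset correlation of 0.01, adjusted over lists and contrasts together, with an estimated correlation and fry as alternatives. CDKN2A is in 2 lists and CDKN1A in 2. Groups, contrasts, lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 1 added alternative, protein-coding genes only.

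Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile normalization, upper quartile scaling, no trend, library weights, a replicate block, only the groups compared, and each library left out in turn. The fit was tested on simulated data with 200 genes changed. It recovered 86 of 100 genes changed by 1 log2 unit and 92 of 100 changed by 2 for BRAF against vector, 84 and 83 for DNMT3B against vector, 84 and 87 for DNMT3B+BRAF against vector, 79 and 91 against BRAF, 84 and 94 against DNMT3B, 85 and 93 for the interaction, and 89 and 85 for the averaged effect, on 17285 genes. False calls were 2.73 to 7.29% of all calls, the most in the interaction. The simulated noise was independent between genes and few genes changed, while the real contrasts called 22.6 to 66.3% of genes. The simulated shares therefore need not hold for the real contrasts. Other splits of the libraries were fitted, all 10 for each pair of groups and 100 drawn for the interaction and averaged effect. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.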

Results

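The libraries measured gene expression by RNA sequencing in IMR-90 cells, a line of human fetal lung fibroblasts. Lentiviral vectors carried the DNA methyltransferase DNMT3B, an oncogenic form of the kinase BRAF that drives fibroblasts into senescence, both, or neither. The 12 libraries fall into 4 groups of 3: empty vector, DNMT3B, BRAF, and DNMT3B+BRAF. The design asks what BRAF and DNMT3B each change, and whether the response to one depends on the other, in a series on DNMT3B and BRAF in intestinal cancer. Values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library. Between 30480 and 33300 genes lay above 0 in a library and 15930 to 16287 reached 1 FPKM. Read numbers per library are not given in the sources used here, so no counting error is given. Median FPKM of the 17285 tested genes was 8.12 to 8.50 per library. Across genes, log2 values of replicates correlated with Pearson r of 0.890 to 0.906, and the median coefficient of variation of the 6716 protein-coding genes with a mean of at least 10 FPKM over the 12 libraries, out of 11713 tested, was 5.45% in vector, 3.11% in DNMT3B, 4.25% in BRAF and 4.05% in DNMT3B+BRAF cells. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Group levels are mean FPKM ± SD with n = 3, and fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

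Transcripts of both introduced genes were high in the libraries whose labels name them. DNMT3B, a de novo DNA methyltransferase, stood at 0.972 ± 0.0818 FPKM in vector, 129.8 ± 0.151 in DNMT3B, 0.909 ± 0.815 in BRAF and 1035 ± 31.6 in DNMT3B+BRAF cells (SD, n = 3). Its level in DNMT3B+BRAF cells was 7.97 times that in DNMT3B cells, a log2 rise of 2.98 (SE 0.22) (limma, Benjamini-Hochberg adjusted p = 1.22e-06) with all 3 libraries of one group above all 3 of the other. BRAF, a kinase upstream of MEK and ERK, stood at 4.88 ± 0.429 FPKM in vector, 5.84 ± 0.109 in DNMT3B, 668 ± 11.3 in BRAF and 529.6 ± 7.82 in DNMT3B+BRAF cells. In BRAF cells this was 137 times the vector level, and DNMT3B+BRAF cells held 0.792 times the level of BRAF cells, a log2 change of -0.34 (SE 0.05) (limma, Benjamini-Hochberg adjusted p = 0.000264). DNMT3B did not pass the test between BRAF and vector cells, with a log2 change of -0.13 (limma, Benjamini-Hochberg adjusted p = 0.639), but leaving out BRAF replicate 1 gave -0.45 (adjusted p = 0.000609). BRAF rose by 0.22 with DNMT3B alone (limma, Benjamini-Hochberg adjusted p = 0.00643), a call that ended when only these 2 groups were fitted (adjusted p = 0.0862). FPKM of a gene does not separate introduced from endogenous transcripts.

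**Figure D1:**
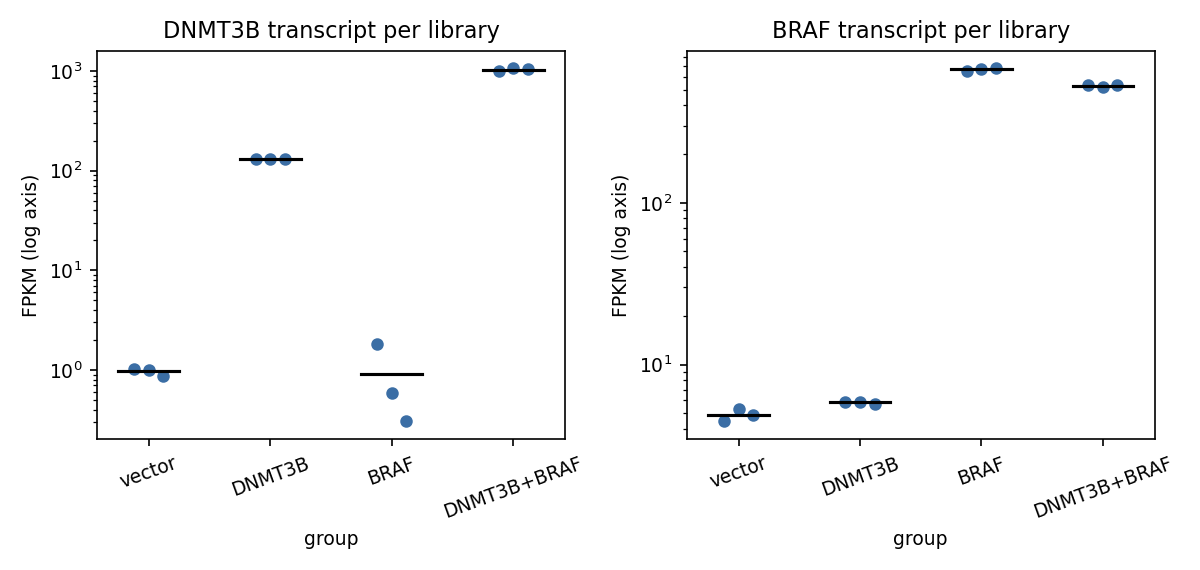
FPKM of DNMT3B (left) and BRAF (right) on a log axis, with 1 point per library and a bar at the mean of the 3 libraries of each group. DNMT3B averaged 130 FPKM in DNMT3B and 1035 in DNMT3B+BRAF cells, and BRAF 668 FPKM in BRAF and 529.6 in DNMT3B+BRAF cells.

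BRAF cells carried a large inflammatory and protease programme and low levels of proliferation, matrix and contractile transcripts. IL1B, an inflammatory cytokine, rose from 2.54 ± 1.01 FPKM in vector to 6506 ± 249.7 in BRAF cells (SD, n = 3), a log2 rise of 10.89 (SE 0.17). IL8, a neutrophil chemokine, rose from 3.69 ± 2.15 to 6918 ± 245, and the matrix-degrading enzyme MMP3 from 3.49 ± 0.766 to 5269 ± 92.6. CCL20, a chemokine, and CSF3, a granulocyte growth factor, were below 1 FPKM in vector and reached 929 ± 7.21 and 823 ± 25.7. Among the genes that fell were HSPB6, a small heat shock protein, from 159 ± 12.4 to 5.94 ± 0.453, KISS1, the kisspeptin precursor, from 525 ± 34.1 to 30.3 ± 0.573, and MEST, an imprinted gene, from 96.8 ± 3.98 to 4.37 ± 0.214. The highest limma Benjamini-Hochberg adjusted p of these genes was 1.58e-10, and in each case no library of one group overlapped the other group. In all, 11458 of 17285 genes changed (limma, Benjamini-Hochberg), 5084 higher and 6374 lower, of which 2608 changed at least 2-fold.

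Of the 37 tested senescence secretory genes, cytokines, growth factors and proteases released by senescent fibroblasts, 34 rose with BRAF and 3 fell, with a median log2 change of 5.50 (limma camera, Benjamini-Hochberg adjusted p = 3.71e-19). That call was lost at adjusted p = 0.0677 with an estimated correlation. CXCL1, CXCL2 and CXCL3 are close in sequence, and how reads were divided between them is not given in the sources used here. Some markers of other cell types rose beside these genes: all 4 tested blood cell markers of 14 listed, led by LAPTM5 from 0.0632 ± 0.0154 to 18.03 ± 0.635 FPKM (camera adjusted p = 0.00467, and adjusted p = 0.0638 with an estimated correlation), and the endothelial receptor TIE1 from 0.400 ± 0.0308 to 44.3 ± 2.22. The other listed blood cell markers did not reach a mean of 1 FPKM. LAPTM5 passed that filter only through libraries with BRAF, so the filter favours members that rise with BRAF and the list test is no independent support. The 5 tested endothelial markers of 11 listed did not pass as a list (adjusted p = 0.175). Nor did the 6 tested epithelial markers of 14 listed (adjusted p = 0.149), of which 4 fell.

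Proliferation genes fell together. All 33 mitosis genes were lower in BRAF than in vector cells (camera, Benjamini-Hochberg adjusted p = 2.43e-14, median log2 change -1.78), among them the spindle factor TPX2 from 29.7 ± 0.361 to 5.53 ± 0.190 FPKM and the mitotic kinase AURKB from 23.7 ± 3.32 to 4.92 ± 0.316. Of 37 DNA replication genes 36 fell and 1 rose (camera adjusted p = 2.01e-11), including thymidine kinase TK1 from 54.1 ± 3.31 to 8.94 ± 0.985 and the lamina gene LMNB1 from 24.1 ± 0.798 to 5.01 ± 0.2998. Among the 12 cell cycle inhibitors 6 rose and 5 fell, and the list as a whole did not pass (adjusted p = 0.534). CDKN2B rose from 3.46 ± 0.288 to 62.7 ± 1.43 and CDKN2A from 9.07 ± 0.462 to 21.2 ± 1.94, while CDKN2C, which acts on the same kinases, fell from 7.30 ± 0.802 to 1.87 ± 0.249.

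Transcripts induced by ERK signalling rose in BRAF cells, 15 of 21, while 5 fell (camera, Benjamini-Hochberg adjusted p = 2.7e-05). DUSP4, a phosphatase that acts on ERK, rose from 0.744 ± 0.0422 to 54.8 ± 0.935 FPKM and the immediate early gene EGR1 from 8.87 ± 0.445 to 122 ± 3.10. Fibrillar matrix genes fell in 21 of 27 cases and rose in 5 (camera adjusted p = 0.000183), with COL1A1, a chain of the main fibrillar collagen, going from 2900.2 ± 158 to 497 ± 5.998 and the collagen crosslinking enzyme LOX from 531 ± 46.3 to 58.4 ± 2.74. Contractile and TGF-beta response genes fell in 13 and rose in 3 of 17 cases (camera adjusted p = 0.00101, and adjusted p = 0.153 with an estimated correlation), such as calponin CNN1 from 164 ± 7.04 to 25.8 ± 1.65. TGFBI of that list was listed at 0 in vector replicate 3 beside 1069 and 1013 FPKM in the other vector libraries.

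Of 20 unfolded protein and amino acid stress genes 18 rose with BRAF (camera, Benjamini-Hochberg adjusted p = 1.06e-06, and adjusted p = 0.0691 with an estimated correlation), among them the chaperone HSPA5 from 253 ± 2.22 to 559 ± 7.33 FPKM. Cholesterol synthesis genes fell in 17 of 21 cases (camera adjusted p = 0.00318), while INSIG1, a regulator of that pathway, rose from 9.66 ± 0.482 to 78.6 ± 0.404. Ribosomal protein genes fell in 41 of 44 cases by a median log2 of -0.38 (camera adjusted p = 4.82e-08, and adjusted p = 0.443 with an estimated correlation). Of 12 housekeeping genes 2 rose and 6 fell, ACTB from 5147 ± 155 to 1587 ± 38.8 and PPIA from 686 ± 35.6 to 337 ± 14.5, and the list did not pass (adjusted p = 0.512). TFRC, another of them, was listed at 0 in vector replicates 1 and 3, BRAF replicate 1 and DNMT3B+BRAF replicate 2, and lay at 38.9 to 64.7 FPKM in the other 8 libraries. Interferon response genes (3 higher and 9 lower of 15) and the DNA methylation machinery (8 higher and 5 lower of 16) did not pass as lists, at adjusted p = 0.239 and 0.591. The methylation machinery had a median of 0.17 and an upward camera direction but a mean of -0.11, and its member UHRF1, which directs maintenance methylation, fell from 22.8 ± 1.10 to 5.43 ± 0.405. In this comparison, counts adjusted over the list alone equalled those over all genes for each of the 20 lists.

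DNMT3B alone changed fewer genes, and most of the changes of at least 2-fold that passed the test were falls. WFDC1, a secreted protease inhibitor family member, fell from 50.7 ± 4.30 FPKM in vector to 8.25 ± 0.573 in DNMT3B cells (SD, n = 3), a log2 change of -2.48 (SE 0.08). KISS1 fell from 525 ± 34.1 to 101 ± 2.30, the growth factor binding protein IGFBP3 from 562 ± 62.9 to 122 ± 1.54, and the adhesion molecule ICAM1 from 47.8 ± 7.35 to 10.5 ± 1.12. MGST2, a microsomal glutathione transferase, fell from 8.37 ± 1.26 to 0.978 ± 0.162. Among genes that rose, the carboxypeptidase CPA4 went from 84.7 ± 3.83 to 307 ± 9.80, the cystine transporter SLC7A11 from 3.45 ± 0.207 to 13.4 ± 0.193 and the pregnancy-specific glycoprotein PSG9, one of a family of close copies, from 5.03 ± 0.202 to 17.8 ± 0.387. The highest limma Benjamini-Hochberg adjusted p among these was 0.00102, with no overlap between the libraries. In all, 4105 genes changed (limma, Benjamini-Hochberg), and 44 rose and 140 fell at least 2-fold. The split of 2528 higher and 1577 lower rested on the scaling: it was 1909 and 1807 with upper quartile scaling and 1877 and 1640 with quantile normalization.

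Matrix genes fell with DNMT3B in 20 of 27 cases and rose in 3 (limma camera, Benjamini-Hochberg adjusted p = 6.67e-14), including COL3A1 from 251 ± 10.6 to 125 ± 3.97 FPKM and the microfibril gene MFAP4 from 22.8 ± 0.675 to 6.77 ± 0.292. Of 17 contractile and TGF-beta response genes 10 fell and none rose past the threshold (camera adjusted p = 2.47e-08), smooth muscle actin ACTA2 going from 465 ± 21.2 to 196 ± 7.85. Cholesterol synthesis genes rose in 16 of 21 cases and fell in 1 (camera adjusted p = 9.03e-08), or 16 and 2 adjusted over the list alone, with HMGCS1, an early enzyme of the pathway, rising from 9.76 ± 0.895 to 19.8 ± 0.829 and the sterol oxidase MSMO1 from 22.3 ± 1.10 to 42.7 ± 0.985. Of 14 epithelial markers listed 6 were tested and 5 of these fell (camera adjusted p = 2.67e-05), while the others did not reach a mean of 1 FPKM. KRT19 went from 32.9 ± 3.32 to 10.8 ± 0.581 and KRT18 from 109 ± 2.68 to 63.6 ± 1.14, in the same libraries in which matrix and contractile genes fell.

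Of the 37 senescence secretory genes 15 fell and 5 rose with DNMT3B alone, or 17 and 5 adjusted over the list alone, with a median log2 change of -0.11 (limma camera, Benjamini-Hochberg adjusted p = 4.9e-06). That call was lost at adjusted p = 0.297 with an estimated correlation. IL6, an inflammatory cytokine, fell from 16.8 ± 4.85 to 6.19 ± 0.526 FPKM and IL11, another cytokine, from 56.8 ± 11.7 to 17.4 ± 0.679. Interferon response genes fell in 7 of 15 cases, such as ISG15 from 71.4 ± 6.23 to 39.8 ± 1.97 (camera adjusted p = 0.000176, and adjusted p = 0.245 with an estimated correlation). ERK pathway output genes rose in 8 of 21 cases, led by the feedback inhibitor SPRY2 from 17.4 ± 1.51 to 31.4 ± 0.687, and fell in 3 (camera adjusted p = 0.0422, and adjusted p = 0.104 with an estimated correlation). The mitosis and DNA replication lists did not pass (adjusted p = 0.249 and 0.949), and adjusted over the list alone 0 mitosis genes and 1 replication gene were higher, against 3 and 3 over all genes. CDKN2A rose from 9.07 ± 0.462 to 16.3 ± 1.74, and its list of inhibitors, 4 higher and 1 lower or 6 and 1 adjusted over the list alone, did not pass (adjusted p = 0.148). The DNA methylation machinery had 4 members higher, none lower past the threshold, and an adjusted p of 0.169. Of 7 tested genes of the CIMP marker list, promoters often methylated in colorectal tumours, 2 rose and 0 fell (adjusted p = 0.386, median 0.00 and mean 0.15), and IGF2 rose from 80.2 ± 1.89 to 114 ± 2.10.

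Among cells with BRAF, those with DNMT3B had lower levels of much of the secretory programme and higher levels of proliferation genes. CXCL5, a neutrophil chemokine, fell from 852 ± 45.0 FPKM in BRAF to 53.7 ± 3.03 in DNMT3B+BRAF cells (SD, n = 3), a log2 change of -3.96 (SE 0.08). IL1RN, the interleukin receptor antagonist, fell from 33.1 ± 1.14 to 1.23 ± 0.220, the gelatinase MMP9 from 91.0 ± 4.21 to 7.43 ± 0.286, and CSF3 from 823 ± 25.7 to 118 ± 3.30. The decoy receptor TNFRSF6B fell from 16.4 ± 1.37 to 0.544 ± 0.307 and the fetal globin HBG2, a near copy of HBG1, from 20.7 ± 0.494 to 0.423 ± 0.129. CPA4 rose from 2.51 ± 1.85 to 32.7 ± 1.30, SBSN, a gene of stratified epithelia, from 3.70 ± 0.205 to 34.0 ± 2.14, and the matrix glycoprotein FN1 from 743 ± 8.27 to 2173 ± 147. The highest limma Benjamini-Hochberg adjusted p among these was 7.45e-06, and none showed overlap between the libraries. CSF3 and FN1 were chosen as list members and the others for the size of their changes. A total of 6537 genes changed (limma, Benjamini-Hochberg), 3873 higher and 2664 lower. At least 2-fold, 209 rose and 447 fell.

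Of the 37 secretory genes 31 fell and 4 rose in DNMT3B+BRAF against BRAF cells, with a median log2 change of -0.89 (limma camera, Benjamini-Hochberg adjusted p = 9.33e-17). That call was lost at adjusted p = 0.0786 with an estimated correlation. IL11 went from 2609.9 ± 69.3 to 467 ± 10.5 FPKM. Levels stayed far above those of DNMT3B cells, with IL1B at 3465 ± 94.6 against 3.04 ± 0.0777. The blood cell marker LAPTM5 fell beside them from 18.03 ± 0.635 to 5.50 ± 0.201 and the endothelial marker CLDN5 from 4.20 ± 0.147 to 0.344 ± 0.0907, while ROBO4, another endothelial marker, rose from 2.51 ± 0.502 to 8.74 ± 0.512. Of 5 tested endothelial markers of 11 listed 4 fell (camera adjusted p = 0.0459, and adjusted p = 0.249 with an estimated correlation). The 4 blood cell markers, 2 higher and 2 lower, did not pass (adjusted p = 0.404).

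Mitosis genes rose in 32 of 33 cases and none fell (limma camera, Benjamini-Hochberg adjusted p = 1.4e-10), by a median log2 of 0.45. TPX2 went from 5.53 ± 0.190 to 9.94 ± 0.494 FPKM, against 29.7 ± 0.361 in vector. Of 37 replication genes 19 rose, such as LMNB1 from 5.01 ± 0.2998 to 8.90 ± 0.340 (camera adjusted p = 0.000183, and adjusted p = 0.094 with an estimated correlation). Cell cycle inhibitors also rose in 8 and fell in 2 of 12 cases, and their list did not pass (camera adjusted p = 0.0618). Cholesterol synthesis genes rose in 12 and fell in 2 of 21 cases, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.0014), with MSMO1 at 15.7 ± 0.942 in BRAF and 39.4 ± 1.45 in DNMT3B+BRAF cells. Matrix genes moved both ways, 13 higher and 11 lower of 27 (camera adjusted p = 0.803, median -0.02, mean 0.01): LOX rose from 58.4 ± 2.74 to 153 ± 13.6 and MFAP4 fell from 16.5 ± 1.30 to 4.97 ± 0.0388. Ribosomal protein genes rose in 16 and fell in 1 of 44 cases (camera adjusted p = 0.00527, and adjusted p = 0.654 with an estimated correlation). ERK pathway output genes did not pass as a list (adjusted p = 0.145), with cyclin CCND1 rising from 184 ± 7.95 to 342 ± 16.7 and DUSP4 falling from 54.8 ± 0.935 to 27.8 ± 1.03. Adjusted over the list alone, matrix genes counted 13 higher and 12 lower and ERK output genes 7 and 12. Counts of the mitosis, replication, cell cycle inhibitor and ribosomal protein lists were the same.

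**Figure D2:**
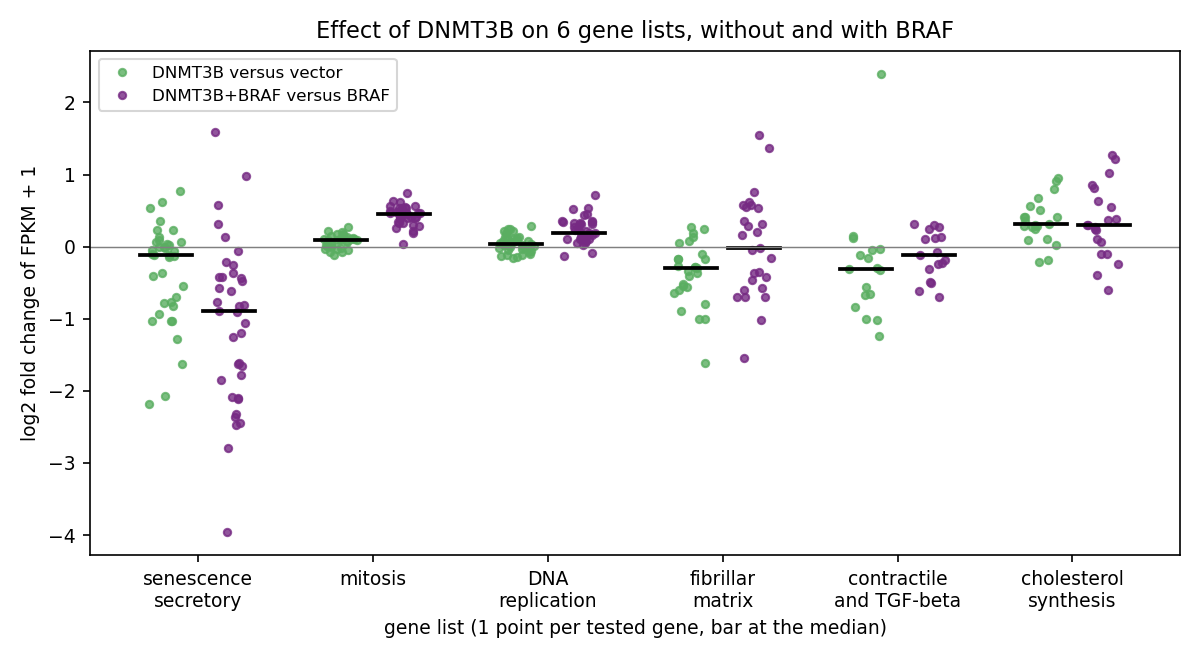
Log2 fold change of FPKM + 1 with DNMT3B for each tested gene of 6 lists, without BRAF (green) and with BRAF (purple), with 1 point per gene and a bar at each list's median. Secretory genes have a median of -0.11 without and -0.89 with BRAF, and mitosis genes 0.10 and 0.45.

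Against vector, cells with both genes had higher levels of secretory genes and lower levels of mitosis genes. IL1B reached 3465 ± 94.6 FPKM against 2.54 ± 1.01 (SD, n = 3), a log2 rise of 9.98 (SE 0.17), and the cytokine TNFSF15 173 ± 0.932 against 0.139 ± 0.0333. HSPB6 fell from 159 ± 12.4 to 4.42 ± 0.265, KRT19 from 32.9 ± 3.32 to 1.12 ± 0.204 and OCIAD2 from 45.3 ± 2.40 to 3.70 ± 0.749. The highest limma Benjamini-Hochberg adjusted p among these was 9.9e-08, with no overlap between libraries. In all, 10809 genes changed (limma, Benjamini-Hochberg), 4981 higher and 5828 lower. Secretory genes were higher in 33 of 37 cases (camera adjusted p = 8.51e-18, and adjusted p = 0.0697 with an estimated correlation) and mitosis genes lower in 33 of 33 (camera adjusted p = 2.43e-14). Beside them all 4 tested blood cell markers of 14 listed were higher (camera adjusted p = 0.00337, and adjusted p = 0.0589 with an estimated correlation). Of 6 tested epithelial markers of 14 listed 5 were lower (camera adjusted p = 0.0354, and adjusted p = 0.138 with an estimated correlation). The filter on mean FPKM favours blood cell markers that rise with BRAF, so their list test is no independent support. Counts adjusted over the list alone were the same for these lists.

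Against DNMT3B cells, DNMT3B+BRAF cells had 36 of 37 secretory genes higher (limma camera, Benjamini-Hochberg adjusted p = 7.55e-26). PTGS2, the inducible prostaglandin synthase, rose from 1.72 ± 0.170 to 401 ± 8.49 FPKM and MMP10, a matrix metalloproteinase, from 0.327 ± 0.0383 to 312 ± 7.07 (SD, n = 3). The oxytocin receptor OXTR fell from 16.2 ± 0.233 to 0.668 ± 0.0613 and the junction gene CLDN11 from 138 ± 0.488 to 12.6 ± 0.533. Adjusted p (limma, Benjamini-Hochberg) was at most 1.94e-10. All 33 mitosis genes were lower, by a median log2 of -1.45 (camera adjusted p = 1.92e-14). ERK pathway output genes rose in 16 of 21 cases, DUSP6, an ERK phosphatase, from 25.6 ± 2.52 to 295 ± 6.89 (camera adjusted p = 2.3e-07). All 4 tested blood cell markers of 14 listed rose beside them (camera adjusted p = 0.00117), where the filter on mean FPKM again favours members that rise with BRAF. In total 10401 genes changed (limma, Benjamini-Hochberg), 4268 higher and 6133 lower. This comparison and BRAF against vector share no library: 3709 genes were higher in both against 1255 for independent lists, 5217 were lower in both against 2262, and 217 went opposite ways against 3378. Their fold changes correlated across genes with r = 0.67 and rho = 0.77, where genes are not independent replicates. Both comparisons use 1 estimate of the spread per gene, which favours calling the same genes in both. The counts for independent lists are therefore only a rough guide.

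**Figure D3:**
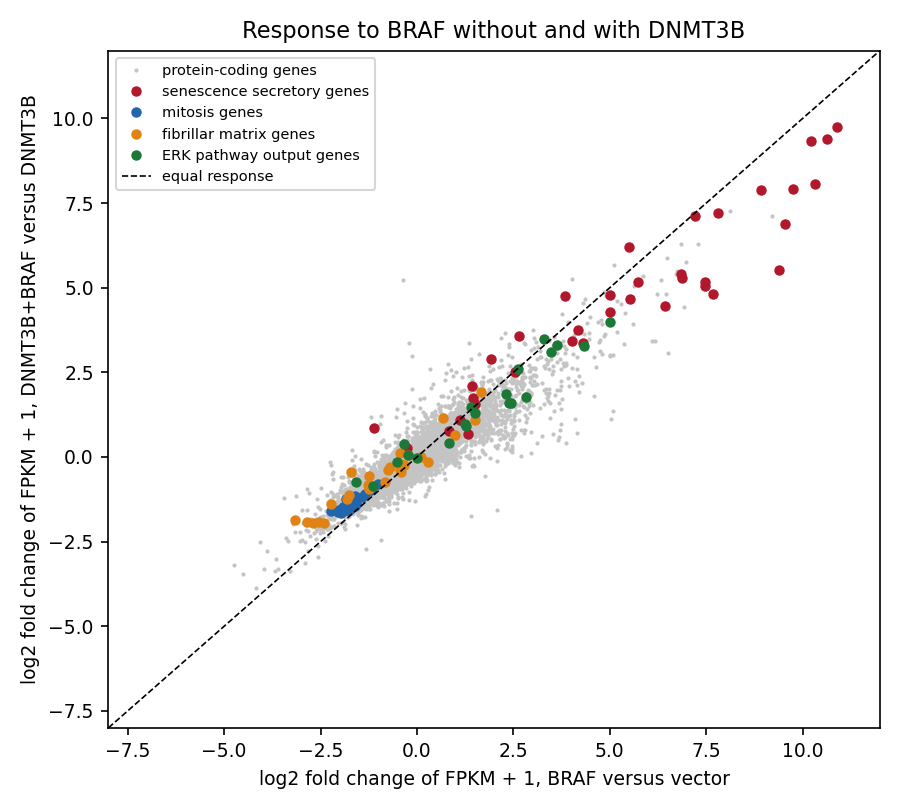
Log2 fold change of FPKM + 1 with BRAF in cells without (horizontal axis) and with DNMT3B (vertical axis), with 1 point per gene, protein-coding genes in grey, members of 4 lists in colour and a dashed line where both are equal. CXCL5 lies at 9.39 without DNMT3B, and the mitosis genes have medians of -1.78 without and -1.45 with DNMT3B.

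The difference between DNMT3B+BRAF and BRAF cells was not the same as that between DNMT3B and vector cells for 3914 genes (limma interaction, Benjamini-Hochberg), 2025 with a positive and 1889 with a negative term. DNMT3B+BRAF cells also held 7.97 times the DNMT3B transcript of DNMT3B cells and 0.792 times the BRAF transcript of BRAF cells, so this term does not separate BRAF status from the levels of the introduced genes. Negative terms lay on SERPINB2, an inhibitor of plasminogen activators (log2 -2.88 (SE 0.08)), CSF3 (-2.65 (SE 0.06)) and CXCL3 (-2.42 (SE 0.09)), a near relative of CXCL1 and CXCL2. CSF3 stood at 0.111 FPKM in vector and 0.0088 in DNMT3B cells, and CXCL3 at 0.104 and 0.0915. At such levels the log2(FPKM + 1) scale leaves little room for a fall without BRAF. The terms of CSF3 and CXCL3 therefore mostly restate the difference between DNMT3B+BRAF and BRAF cells. Positive terms lay on LOX (1.30 (SE 0.11)), FN1 (1.27 (SE 0.08)) and the surface glycoprotein THY1 (0.94 (SE 0.06)). The highest limma Benjamini-Hochberg adjusted p of these genes was 2.09e-05. Among list members the terms were negative for 22 and positive for 9 of 37 secretory genes, but 6 and 6 among the 16 of these at 10 FPKM or more in vector cells, with a median of -0.02. They were positive for 19 of 33 mitosis genes or 27 adjusted over the list alone, positive for 17 and negative for 3 of 27 matrix genes, and negative for 7 and positive for 5 of 21 ERK pathway output genes. Adjusted over the list alone, matrix genes counted 18 positive and 3 negative and ERK output genes 8 negative and 5 positive.

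Averaged over BRAF status, 6766 genes differed with DNMT3B (limma, Benjamini-Hochberg), 4249 higher and 2517 lower. The split was 3644 and 2803 with upper quartile scaling and 3801 and 2716 with quantile normalization. SEMA3F, a secreted semaphorin, was at 17.5 ± 0.311 FPKM in vector, 4.68 ± 0.304 in DNMT3B, 37.3 ± 0.511 in BRAF and 5.23 ± 0.405 in DNMT3B+BRAF cells, and NDUFA4L2, which encodes a mitochondrial protein, at 6.48 ± 0.564, 0.790 ± 0.0904, 6.70 ± 0.412 and 0.455 ± 0.0336 (SD, n = 3). RARRES2, which encodes chemerin, changed by -2.20 on the log2 scale and SLC7A11 rose by 1.43. Each of these genes had a limma Benjamini-Hochberg adjusted p of at most 9.13e-08. Cholesterol synthesis genes were higher in 15 and lower in 1 of 21 cases (limma camera, Benjamini-Hochberg adjusted p = 3.98e-06), and secretory genes lower in 31 and higher in 3 of 37 (adjusted p = 8.78e-19, and adjusted p = 0.068 with an estimated correlation). Adjusted over the list alone these counts were 16 and 1, and 33 and 3. Epithelial markers, 6 tested of 14 listed, were lower beside them in 5 cases, over the list alone too (camera adjusted p = 0.00258, and adjusted p = 0.0628 with an estimated correlation). Of 12 cell cycle inhibitors 7 were higher and 0 lower past the threshold (camera adjusted p = 0.0184, and adjusted p = 0.0834 with an estimated correlation). Adjusted over the list alone, 8 inhibitors were higher and 0 lower. Several of the largest rises were short RNA genes such as RNU6 copies, whose FPKM is unstable. The effects of DNMT3B without and with BRAF share no library but use 1 estimate of the spread per gene, which favours calling the same genes. They were both positive for 1312 genes against 566 for independent lists, both negative for 812 against 243, and opposite for 466 against 743. Their correlation across genes was r = 0.16 and rho = 0.29. SYCP3, the only germline gene tested, stood at 1.21 ± 0.348 in vector and 1.42 ± 0.461 in DNMT3B cells and passed in none of the 7 contrasts (lowest limma Benjamini-Hochberg adjusted p = 0.248).

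Over the 20 lists and 7 contrasts, 70 of 140 camera tests passed with the preset correlation and 26 of these also with an estimated one. In BRAF against vector the latter were replication, mitosis, ERK output, matrix and cholesterol genes. In DNMT3B against vector they were matrix, contractile, cholesterol and epithelial genes, and in DNMT3B+BRAF against BRAF mitosis and cholesterol genes. DNMT3B+BRAF against vector kept replication, mitosis, ERK output and matrix genes, and against DNMT3B secretory, replication, mitosis, ERK output, cholesterol and blood cell genes. The blood cell call rests on 4 tested members of 14 listed, and LAPTM5 among them passed the filter only through libraries with BRAF. The interaction kept mitosis, matrix and hypoxia genes, and the averaged effect mitosis and cholesterol genes.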

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

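The splits of the libraries and the effect of scaling on the BRAF response were tests set before their results were seen, and the tests of a cell fraction, of BRAF dose, of both accounts of the DNMT3B transcript and of the share of higher genes, and the choice of genes by their averaged BRAF response, were chosen only after.

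The results listed here were picked out because the difference with DNMT3B was not the same in cells with and without BRAF by the limma interaction test with Benjamini-Hochberg adjustment, as for 3914 genes, though the levels of both introduced transcripts also differ between these cells. The largest positive interactions on the log2 scale were DNMT3B itself at 3.11, RNU6-11P, a short RNA copy, at 2.48, LINC00659 at 2.43, ACOX2 at 2.36, MYH16 at 2.35, GPRC5A at 2.26, KRT23 at 2.25, WISP1 at 2.15, PRR4 at 2.14 and NID2 at 2.10. The largest negative ones were RNU6-446P, another short RNA copy, at -5.70, IL1RN at -3.90, CXCL5 at -3.85, SERPINA9 at -3.72, MMP9 at -3.46, HBG2 at -3.44, ADRA2A at -3.43, SERPINB7 at -3.17, FGF16 at -3.16 and SERPINB4 at -3.10. MMP9 was listed at 0 in vector cells, ADRA2A in DNMT3B cells, FGF16 and SERPINB4 in both, and RNU6-446P outside BRAF cells. CXCL5 stood at 0.280 FPKM in vector and 0.178 in DNMT3B cells, where the scale leaves little room for a fall. The interaction of the BRAF transcript was -0.56. HBG2 and SERPINB4 have near copies, HBG1 and SERPINB3. NID2, a basement membrane protein, stood at 185 ± 15.4 FPKM in vector, 83.3 ± 2.33 in DNMT3B, 38.0 ± 1.09 in BRAF and 74.8 ± 2.61 in DNMT3B+BRAF cells, and KRT23, a keratin, at 0.0629 ± 0.0406, 0.124 ± 0.0755, 0.346 ± 0.0139 and 5.81 ± 0.609 (SD, n = 3).

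List interactions passed by limma camera with Benjamini-Hochberg adjusted p of 9.78e-07 for senescence secretory, 0.000465 for DNA replication, 1.62e-10 for mitosis, 0.0354 for ERK pathway output, 1.71e-08 for fibrillar matrix, 5.78e-05 for contractile and TGF-beta response, 0.0268 for CIMP marker, 0.026 for p53 target, 0.00125 for lysosome and autophagy, 2.85e-07 for hypoxia and glycolysis, 0.0114 for unfolded protein and amino acid stress and 0.00827 for epithelial genes. Median interactions were -0.61, 0.17, 0.34, -0.28, 0.39, 0.41, -0.37, 0.09, 0.14, 0.39, -0.19 and 0.53 in that order. With an estimated correlation, adjusted p was 0.021 for mitosis, 0.0141 for matrix and 0.0437 for hypoxia genes, and between 0.079 and 0.294 for the other lists.

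For a part of the genes the response to BRAF was weaker in cells with DNMT3B: of 2761 genes with a BRAF response of at least 2-fold averaged over cells with and without DNMT3B, 1086 had an interaction towards a smaller response, 156 towards a larger one and 1519 none past the threshold. The slope of the interaction on the averaged BRAF response was -0.173 with upper quartile scaling, -0.169 as deposited and -0.166 with quantile normalization. It was -0.222 to -0.107 leaving out 1 library. A factor per library shifts nearly all genes alike on the log2 scale. Upper quartile scaling could therefore hardly move this slope, and its result cannot decide on such a difference in scaling. Quantile normalization, which also evens out the spread of values between libraries, left the slope near its deposited value. A candidate explanation is a fraction of DNMT3B+BRAF cells without the BRAF construct. That would place each gene at the fraction of the BRAF transcript, 0.790 ± 0.0251 (SE). However, 28.8% of 11447 changed genes, and 51.4% of the 2597 changed at least 2-fold, lay over 3 standard errors from it. Taken as ratios, with a BRAF transcript fraction of 0.659, the shares were 26.1% of 11363 and 46.8% of 2515 genes. A fraction of cells does not account for those genes alone and stays open for the rest. The bound for excluding it, over 50% of all changed genes, was not reached by levels or by ratios. Only the subset changed at least 2-fold passed 50%, and only by levels. A lower dose of BRAF, whose transcript changed by -0.34 on the log2 scale, cannot be told apart from an effect of DNMT3B because both change in the same 3 libraries.

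The DNMT3B transcript in DNMT3B+BRAF cells was 7.97 times its level in DNMT3B cells. Scaling was argued against, since the median of all genes moved by -0.0742 while DNMT3B rose by 2.98. A rise of the endogenous gene with BRAF was also argued against, since the DNMT3B level in BRAF cells was 0.1004% of the 904.9 FPKM difference. Copy number of the construct and the activity of its promoter in BRAF cells may differ and were not tested.

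More genes were higher than lower with DNMT3B alone, 61.6% of those called. That share was 51.4% with upper quartile scaling and 53.4% with quantile normalization, so the excess may come from scaling between libraries. A real shift of many genes by small amounts would look alike in these values and was not tested.

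For the interaction, 1 of 100 splits, the real one, gave as many genes as the real 3914, and the highest other split gave 3211. Such high values came from 13 splits that kept the true groups of 1 background, and splits that mixed both gave at most 44. Mixing a background leaves only a part of its difference with DNMT3B and moves the rest into the spread between libraries. The splits therefore argue against chance splits for a difference with DNMT3B, and do not test whether that difference changes with BRAF. For the averaged effect 1 of 100 splits reached the real 6766, with 3192 as the highest other. The pairs of groups allow only 10 splits each, too few for a share under 0.05, with real values and highest others of 11458 and 7 for BRAF against vector, 4105 and 3 for DNMT3B against vector, 10809 and 3 for DNMT3B+BRAF against vector, 6537 and 3 for DNMT3B+BRAF against BRAF, and 10401 and 9 for DNMT3B+BRAF against DNMT3B.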

How the results depend on the processing

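The alternative of protein-coding genes only was chosen after seeing the data. All 7 counts of changed genes stayed within 1.5 times their values under each of the alternatives run. The share of higher genes was less stable and left its 95% binomial interval in 7 contrasts without a filter. It did so in 6 at a mean of at least 5 FPKM and 6 with protein-coding genes only. Upper quartile scaling moved it in 5 and quantile normalization in 5. Among results of named genes, 254 lost their call leaving out 1 library and 7916 stayed. Without a filter 32 lost it and 649 stayed. Leaving out 1 library gave 10863 to 11457 genes for BRAF against vector, 3116 to 4127 for DNMT3B against vector, 10238 to 10835 for DNMT3B+BRAF against vector, 5693 to 6770 against BRAF, 9663 to 10531 against DNMT3B, 3339 to 3830 for the interaction and 6150 to 6677 for the averaged effect. The same replicate numbers did not pair the libraries: 18 same-number pairs correlated at -0.0901 to 0.0871 and 1 library correlated best with its own number. A replicate block gave 11257, 3712, 10619, 6288, 10219, 3574 and 6470 genes in the same order. Quantile normalization turned ACTB in DNMT3B against vector to 0.18 (adjusted p = 0.176) and CLDN5 in DNMT3B+BRAF against DNMT3B to -0.0015 (adjusted p = 1). The fry test, which asks only whether a list moves on balance one way, gave the opposite direction for the DNA methylation machinery with BRAF against vector (adjusted p = 1.86e-05), DNMT3B+BRAF against vector (0.0186) and against DNMT3B (0.000121), and for the unfolded protein list in the averaged effect (0.000582). The averaged change of the BRAF transcript, -0.06, passed with log2(FPKM + 5) at -0.10 (adjusted p = 0.00453) and without vector replicate 1, within -0.0838 to -0.0311 over single libraries left out. With only the 2 groups compared, BRAF with DNMT3B alone stayed at 0.22 and no longer passed (adjusted p = 0.0862). DNMT3B in BRAF against vector ranged from -0.45 without BRAF replicate 1 to 0.11 without BRAF replicate 3. With an estimated correlation 44 list calls were lost and 96 list results stayed. Where results changed, the cause was not tested.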

Other observations

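In this part, both tests of hypotheses on the BRAF response were chosen only after the result was seen.

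Glycolytic and lysosomal genes also moved. Of 18 hypoxia and glycolysis genes 11 were higher and 4 lower in DNMT3B+BRAF than in BRAF cells (limma camera, Benjamini-Hochberg adjusted p = 0.00557, and adjusted p = 0.206 with an estimated correlation). Lactate dehydrogenase LDHA stood at 1393 ± 12.4 FPKM in vector, 733 ± 3.66 in BRAF and 1294 ± 39.9 in DNMT3B+BRAF cells, the glucose transporter SLC2A1 at 227 ± 7.88, 64.5 ± 1.66 and 111 ± 4.65, and NDRG1, a stress-responsive gene, at 106 ± 4.51, 157 ± 0.591 and 265 ± 5.69 (SD, n = 3). The phosphofructokinase regulator PFKFB4 moved the other way, from 28.3 ± 0.396 in BRAF to 11.4 ± 0.366 in DNMT3B+BRAF cells. Of 24 lysosome and autophagy genes 15 were higher and 5 lower in that comparison (adjusted p = 0.0354, and adjusted p = 0.249 with an estimated correlation). The protease CTSB stood at 675 ± 13.1 in vector, 943 ± 8.93 in DNMT3B, 1024 ± 25.7 in BRAF and 2362 ± 58.5 in DNMT3B+BRAF cells, and the collagen-degrading CTSK at 11.5 ± 0.760, 5.70 ± 1.02, 27.5 ± 1.23 and 8.15 ± 0.559. Adjusted over the list alone, the counts were the same.

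Among p53 target genes, 11 rose and 9 fell of 24 with BRAF (limma camera, Benjamini-Hochberg adjusted p = 0.458), and GDF15, a stress cytokine, stood at 70.7 ± 5.02 FPKM in vector, 37.6 ± 2.80 in DNMT3B, 591 ± 17.0 in BRAF and 357 ± 15.2 in DNMT3B+BRAF cells. SESN2, another target that also answers amino acid stress, stood at 12.8 ± 0.370 in BRAF and 25.6 ± 1.07 in DNMT3B+BRAF cells. In the CIMP list CRABP1, a retinoic acid binding protein, was listed at 0 in vector and DNMT3B cells and stood at 4.55 ± 0.448 in BRAF and 0.118 ± 0.135 in DNMT3B+BRAF cells, while SOCS1, a cytokine signalling inhibitor, stood at 7.88 ± 0.710, 7.31 ± 0.610, 1.98 ± 0.582 and 4.82 ± 0.258 in vector, DNMT3B, BRAF and DNMT3B+BRAF cells. DNA methylation was not analysed here.

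The weaker BRAF response might be one proportional scaling of the whole response. If so, ERK output and secretory genes should keep the same proportion of their log2 response. Among members that rose at least 2-fold with BRAF, ERK genes kept 82.7% ± 14.1 (SD) over 14 members and secretory genes 91.4% ± 23.5 over 33. This leaves out the members that fell. A two-sided permutation test of list membership gave p = 0.208 (100000 permutations), which does not show that the lists are equal. It treats genes as independent though all come from the same libraries, so its p does not measure the spread between libraries. Choosing members by their change in BRAF against vector cells lowers the kept proportion of both lists, so neither is set against 100%. Over the 2761 genes chosen by their averaged BRAF response, the median kept proportion was 78.2%.

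Alternatively, DNMT3B may lower secretory genes by the same amount with and without BRAF, which low levels in vector cells could hide. Over 16 secretory genes at 10 FPKM or more in vector cells, the median interaction was -0.0195, with 9 below 0 and 7 above, 6 of each past the threshold, and a range from -0.92 to 1.97. With DNMT3B alone 9 of them were lower, in BRAF cells 13, and 8 in both. The 6 terms past the threshold on each side argue against the same amount for those genes, and terms of opposite sign can give a median near 0. Of the 21 members below that level, 16 had an interaction below 0 past the threshold. There a low starting level leaves little room to fall, so the explanation stays open for those 21 members.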
